A study of Homo sapiens with 528 samples.

How the data were processed

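The samples are 528 Affymetrix array measurements of total RNA from 59 established tumor cell lines of the NCI-60 panel. Per the labels' protocols, lines were grown in RPMI-1640 medium, plated a day before treatment, and given vorinostat dissolved in DMSO at 0, 1000 or 5000 nM for 2, 6 or 24 h. The 0 nM arrays are the vehicle controls of their own time. RNA was labelled with biotin by a kit of 1 amplification cycle, per the labels. Line, dose and time were read from each sample's title and the tissue of origin from its characteristics, and every column of the table was matched to 1 sample by its name, with 0 columns left over.

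The values are log2 expression levels as deposited by the authors in the table of the whole series, 22277 probe sets per array. How the scanned images were summarised into these levels and normalized is not given in the sources used here, so the size of a change may depend on steps that cannot be checked. Values ran from 2.94 to 14.43 with 0 missing, array medians from 5.444 to 5.872 (median 5.686), and the interquartile range of an array had a median of 4.27. No array was identical to another. No scale or centring step was added, since array medians lay close together. Arrays give no read depth, and their number limits the precision.

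Probe sets were named with the platform's annotation: 19070 had 1 gene symbol, 1043 had several and 2164 had none. A gene ID in the RefSeq table was found for 19058, and 0 symbols changed. Probe sets with several symbols were named after none of them and left out. Each of 11963 genes was represented by its probe set with the highest mean over all arrays, and 4310 genes had more than 1. There were 62 control probe sets, of which those for ACTB and GAPDH have a gene symbol, and the 2108 probe sets that were neither named nor controls were tested apart.

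Each line served as its own control. For each gene the log2 level of the untreated array of the same line and time was subtracted from that of the treated array, and limma's lmFit and eBayes with a mean-variance trend tested the mean of these differences over lines, two-sided, with Benjamini-Hochberg adjustment over all genes. A gene was called with an adjusted p under 0.05 and a mean change of at least 1.5-fold. Doses were compared by the same test on the difference of treated arrays, times by the difference of differences, and untreated arrays at 24 and 2 h directly. Tissues were compared at 5000 nM and 24 h with limma's F-test over 9 tissues (adjusted p under 0.05, no minimum size), and leukemia lines with all others. Every adjusted p of a gene comes from limma.

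The pairing comes from the cell line name. After the group means were removed, arrays of the same line at both doses being compared had median correlations of 0.97, 0.94 and 0.93 (1000 and 0 nM at 2, 6 and 24 h) and 0.96, 0.92 and 0.81 (5000 and 0 nM), against -0.05 to -0.03 between lines. RXF-393 at 5000 nM (-0.25 at 2 and 6 h) and T-47D at 5000 nM and 24 h (-0.21) were below 0.

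Gene lists, 37 with 662 entries of which 575 were measured (20 through an older symbol), the tests, the named genes and most alternatives were fixed before the data were examined. The lists are those of the report, from CDK inhibitors to 6 sets of lineage markers. They were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 37 lists of a comparison, and again with an estimated correlation. With the latter only 2 calls held, the CDK inhibitor list at 2 h and the histone acetyltransferases at 6 h, both at 5000 nM. Lineage markers were tested in lines of 1 tissue and adjusted over 6 tests.

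Named genes were, for 5000 nM against 0 nM, the 10 largest rises and 10 largest falls among called genes whose direction held in at least 80% of lines. For other comparisons 5 of each were taken, and for the tissue test the 10 smallest p. From each list up to 4 members with the largest change at 5000 nM and 24 h were named, with HDAC1, HDAC2, HDAC3, HDAC6 and CDKN1A. Other list members named at 2 or 6 h or within a tissue, ODC1, CDKN1B, ERAP1, GPNMB and those named in the closing observations were chosen after their values were seen.

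The similarity of arrays was checked as the correlation over genes of each array's levels minus each gene's mean over all arrays, and arrays nearest to a line known to share their origin (SNB-19 and U251, NCI-ADR-RES and OVCAR-8, MDA-MB-435 and M14) were not counted. In the 47 lines whose arrays, apart from any of these, were all nearest to their own name, the median correlation with own arrays of other times was 0.936. That with the nearest other line was 0.484. The 12 other names stayed in all main results, since labels were not changed from values.

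The response size of a line was its root mean square log2 difference over all genes. Its differences between tissues were tested by permuting the Kruskal-Wallis statistic with 100000 resamples. Shared controls were allowed for by splitting the lines at random between the doses and by simulated unchanged groups, with 100 draws.

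The tests were tried on simulated data with 200 changed genes, 50 for each of 4 fold sizes. For 5000 nM against 0 nM at 24 h they called 100% of the genes changed 2-fold and 4-fold and 0% of those changed 1.25-fold. Of genes changed 2-fold and 4-fold in leukemia lines alone 74% and 98% were called, and in the tissue test 38% and 86%. With a shift added to 1 list, camera found it at 5000 nM and 24 h, and also called 6 of 36 lists that had not been shifted with the preset correlation and 0 with an estimated one.

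Alternatives were no line block, no minimum size, a 2-fold minimum, the mean of all probe sets, the lowest 40% of genes left out, quantile normalization, median centring, eBayes without trend, the Wilcoxon signed-rank test, 1 fit of all 9 groups, leaving out lines, and other line sets. Arrays missing here (A498 at 5000 nM and 6 h, SW-620 at 1000 and 5000 nM and 6 h) left 57 lines with all 9. Tools were R 4.3.3 with limma 3.58.1 and version 1.17.8 of data.table, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.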

Results

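Gene expression was measured on Affymetrix arrays in 59 human tumor cell lines of the NCI-60 panel, a set of established lines kept for testing anticancer compounds. The lines come from 9 tissues of origin: 6 breast, 6 central nervous system (CNS), 7 colon, 5 leukemia, 9 lung, 9 melanoma, 7 ovarian, 2 prostate and 8 renal lines. Each line was exposed to vorinostat, an inhibitor of histone deacetylases that is used against cutaneous T-cell lymphoma, at 0, 1000 or 5000 nM for 2, 6 or 24 h. There was 1 array per line, dose and time. A498 has no array here at 5000 nM and 6 h, and SW-620 has none at 1000 or 5000 nM and 6 h. The comparisons ask how expression changed with the drug in each line, how the change depended on dose and time, and where tissues differed. The number of arrays limits the precision, and p-values measure the spread between lines, since no line was measured more than 1 time per dose and hour.

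Values are the deposited log2 levels of 11963 genes, 1 probe set per gene. A gene was called changed when its Benjamini-Hochberg adjusted p from limma, run on the differences within each line, was under 0.05 and its mean change was at least 1.5-fold. Changes are given as means on the log2 scale ± SD over lines. Leaving aside arrays nearest to a line of known shared origin, 24 arrays were nearer in expression to another line name than to any array of their own. They belong to 12 line names: BT-549, HCT-116, LOX, M14, NCI-H226, OVCAR-8, RXF-393, SK-MEL-2, SK-MEL-5, SK-OV-3, T-47D and TK-10. The count may be too low, since arrays of 1 label that were out of place together could match each other. Under RXF-393 only 1 array was counted. Yet its untreated 6 h array correlated at 0.936 with BT-549 and at -0.271 with its own 2 h array. Names that hold the same cells would not be independent lines, so the number of lines in a test may be too high. The gene count of each test without these 12 names, chosen after seeing the data, stands beside that over all lines.

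The first comparison asks what 5000 nM vorinostat changed within 2 h. FOS, a transcription factor of the immediate early response, rose 3.0-fold (1.59 ± 0.72, n = 59) and was higher in 58 of 59 lines. VAMP1, a SNARE protein of vesicle fusion, rose 2.36-fold (1.24 ± 0.51) in all 59 lines, and DDIT4, an inhibitor of mTORC1 signalling, rose 2.24-fold (1.17 ± 0.87) in 55 lines. LIF, a cytokine, fell 2.08-fold (-1.05 ± 0.85) in 52 lines, KLF11 fell 1.99-fold (-0.99 ± 0.52) in 57, and NFKBIA, which holds NF-kappaB in the cytoplasm, fell 1.95-fold (-0.96 ± 0.39) in all 59. In these 6 genes the mean change was larger than the SD over lines.

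Other genes that rose at 2 h were the repressor BCL6 (1.13), PLEKHF1 (1.07), ZNF324 (1.03), OSR2 (0.96), ING1, a subunit of a histone deacetylase complex (0.94), IER5 (0.92) and TRIM52 (0.90). ZBTB1 (-0.94), TRIM13 (-0.90), COX20 (-0.81), the Cajal body protein coilin (COIL, -0.79), SPRY2, an inhibitor of receptor tyrosine kinase signalling (-0.74), and ZNF140 (-0.74) fell. CEBPD also fell (-0.78), but the mean over all its probe sets was -0.46, under the 1.5-fold minimum. Among 22 measured immediate early genes 4 rose, FOS, IER5, DUSP5 (0.80 ± 0.53) and ZFP36 (0.64 ± 0.56), 2 fell, MYC (-0.72 ± 0.62) and KLF6 (-0.64 ± 0.56), and 16 did neither. Among 14 CDK inhibitors and growth arrest genes CDKN2D (0.77 ± 0.41), GADD45B (0.87 ± 0.96) and TOB1 (0.85 ± 0.44) rose, and the mean of the list was higher in 58 of 59 lines. MYC was also the 1 member of 18 ribosome biogenesis genes that fell.

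In all, 95 genes passed at 2 h and 5000 nM, 61 higher and 34 lower, 0.794% of the genes tested. Without the 12 line names 82 passed. limma's camera, which asks whether a list moved more than the other genes, called the CDK inhibitor list (adjusted p = 0.00027), and it was called at adjusted p = 0.020 with an estimated correlation too. The other 8 lists called at this time, the immediate early list among them (adjusted p = 0.00033), had adjusted p = 0.081 or more with an estimated correlation. The list of the unfolded protein and integrated stress response (adjusted p = 0.030) did not pass without the 12 line names (adjusted p = 0.10).

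**Figure D1:**
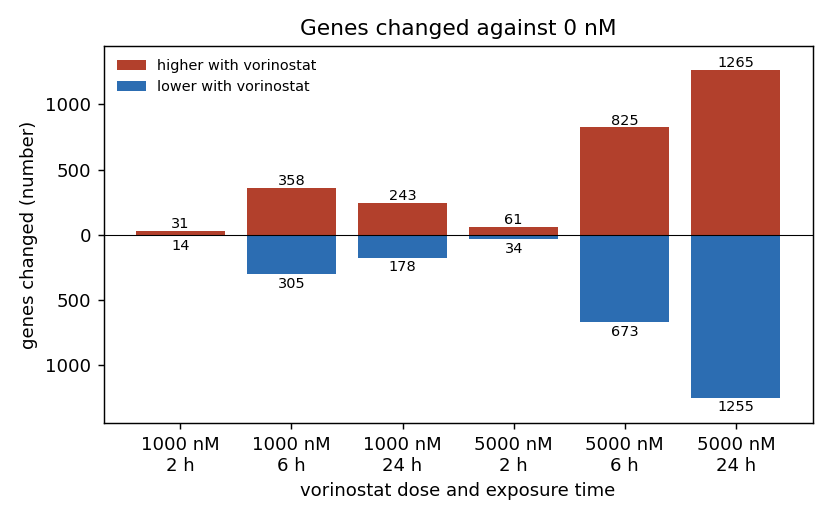
Number of genes called changed against 0 nM (y axis), for each vorinostat dose and exposure time (x axis). Bars above 0 count genes that were higher with the drug and bars below 0 genes that were lower, and at 5000 nM they run from 61 and 34 genes at 2 h to 1265 and 1255 at 24 h.

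The second comparison asks the same at 5000 nM and 6 h, in 57 lines. RGL1, an exchange factor for the GTPase Ral, rose 7.42-fold (2.89 ± 0.81) and was higher in all 57 lines. DHRS2, a short-chain dehydrogenase, rose 6.00-fold (2.58 ± 1.87), and TUFT1 rose 4.91-fold (2.30 ± 0.86). MEPCE, the enzyme that caps the 7SK RNA, fell 3.84-fold (-1.94 ± 0.35) in every line. KEAP1, the adaptor that marks NRF2 for degradation, fell 3.80-fold (-1.93 ± 0.55) in 56 lines, and GINS3, a part of the replicative helicase, fell 3.61-fold (-1.85 ± 0.40) in 57.

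CRISPLD2 (2.24), the secreted glycoprotein STC1 (2.22), FOS (2.12), the actin-binding protein CORO1A (2.12), KIAA0513 (2.05), ABAT, which breaks down the transmitter GABA (2.05), and the Notch target HEY1 (2.02) also rose. ZBTB1 (-2.02), PRDM10 (-1.91), ZFX (-1.88), the chromatin protein ADNP (-1.87), LIF (-1.83), JADE2 (-1.82) and CASD1 (-1.80) fell, each in at least 53 lines. HDAC3, a direct target of vorinostat, rose 1.64-fold (0.71 ± 0.24) in all 57 lines, and CDKN1A, the CDK inhibitor p21, rose 2.40-fold (1.27 ± 0.90) in 52, after 0.32 ± 0.57 at 2 h, which did not pass.

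Of 12 measured histone acetyltransferases 5 fell and 0 rose. KAT6B (-1.47 ± 0.46), CREBBP (-1.30 ± 0.35), KAT5 (-1.19 ± 0.42) and KAT7 (-1.06 ± 0.32) were lower in each of the 57 lines. The list passed camera (adjusted p = 0.00025, and adjusted p = 0.045 with an estimated correlation). Of the 22 immediate early genes 12 rose, with ATF3 at 1.32 ± 0.74, DUSP5 at 1.25 ± 0.88 and DUSP1 at 1.08 ± 0.76, and 3 fell, FOSL1 (-1.59 ± 1.01), MYC (-1.09 ± 0.78) and KLF6. That list had adjusted p = 0.00095, and adjusted p = 0.30 with an estimated correlation. Of 14 genes of cholesterol synthesis and uptake 6 rose, led by INSIG1, an endoplasmic reticulum retention factor for the sterol sensor SCAP (1.02 ± 0.57), IDI1 (0.88 ± 0.26) and HMGCS1 (0.79 ± 0.40), with adjusted p = 0.00025 for the list, and adjusted p = 0.30 with an estimated correlation. Of 13 genes in the list named for replication-independent and linker histones 6 rose, H1-10 by the most (1.16 ± 0.42), and the list did not pass (adjusted p = 0.073). Despite its name the list also holds genes of the histone clusters, among them H1-2, H2BC21, H2BC5 and H2AC6. The rises of H1-2 (0.65), H2BC5 (0.59) and H2AC6 (0.62), counted among the 6, did not pass without the 12 line names, at 0.28, 0.33 and 0.35.

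Mitosis genes began to fall by 6 h, 11 of 26, with PLK1 at -1.24 ± 0.54 and AURKA at -1.15 ± 0.52, 2 kinases of the mitotic spindle (adjusted p = 1.7e-05 for the list, adjusted p = 0.43 with an estimated correlation). Among 28 DNA replication genes 6 fell, CTPS1 (-1.13 ± 0.46), the origin licensing factor CDT1 (-1.01 ± 0.52) and POLE2 (-0.85 ± 0.69) the most (adjusted p = 2.4e-05, adjusted p = 0.43 with an estimated correlation). TYMS (-0.68) and MCM5 (-0.82), counted among these 6, did not pass without the 12 line names, at -0.35 and -0.58. In the anti-apoptotic list CFLAR, which blocks caspase-8 (-1.09 ± 0.54), BCL2L1 (-0.82 ± 0.48) and XIAP (-0.59 ± 0.39) fell and none of 9 rose, and the list did not pass (adjusted p = 0.073).

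At 6 h and 5000 nM 1498 genes passed, 825 higher and 673 lower, or 12.5% of the genes tested. Without the 12 line names 1387 passed, and with each array median-centred 741 genes were higher and 758 lower. The arrays labelled RXF-393 differed from their untreated arrays at 2 and 6 h by a root mean square of 1.244 and 1.253 log2 units over all genes, against medians of 0.246 and 0.507 over lines.

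The third comparison asks which genes were changed at 5000 nM and 24 h. DHRS2 (probe set 214079_at) rose the most, 22.1-fold (4.46 ± 2.23, n = 59), and was higher in 54 of 59 lines. It was not higher under the labels HCT-116, M14, NCI-H226, SK-MEL-5 and SK-OV-3, all among the 12 line names. ABAT rose 10.4-fold (3.38 ± 1.60), SERPINI1, the neuronal protease inhibitor neuroserpin, 9.22-fold (3.20 ± 1.84), and HPCAL4, a neuronal calcium sensor, 7.95-fold (2.99 ± 1.47). TYMS, the enzyme that makes thymidylate for DNA synthesis, fell 5.73-fold (-2.52 ± 1.28) in 57 lines from an untreated level of 12.28. NMI fell 6.27-fold (-2.65 ± 1.26), NSMAF 5.90-fold (-2.56 ± 1.05) and SERPINH1, a chaperone of collagen folding, 5.79-fold (-2.53 ± 1.33).

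Further rises were those of ENPP2, the secreted lipid enzyme autotaxin (2.79 ± 1.85), the secreted chaperone clusterin (CLU, 2.66 ± 1.71), STC1 (2.64 ± 2.39), the linker histone H1-2 (2.52 ± 1.49), CRISPLD2 (2.52 ± 1.60) and SLC17A7, a vesicular glutamate transporter (2.46 ± 1.69). Further falls were those of FAIM (-2.41 ± 1.03), ADI1 of the methionine salvage pathway (-2.37 ± 1.09), the chromatin architectural protein HMGA2 (-2.28 ± 1.69), TLCD3A (-2.28 ± 1.00), the kinetochore protein PMF1 (-2.24 ± 0.85) and JADE2 (-2.22 ± 1.08). TLCD3A and PMF1 were lower in all 59 lines.

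**Figure D2:**
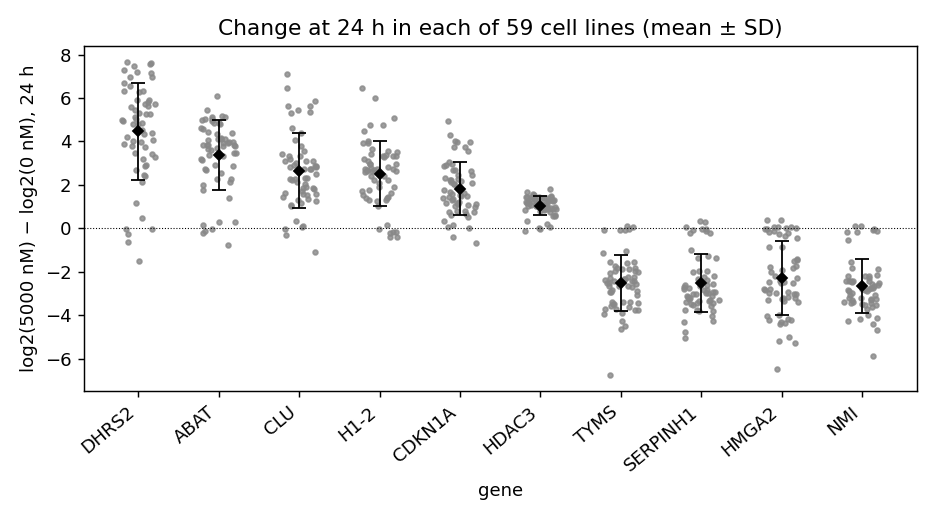
Change of 10 genes at 24 h in each of the 59 cell lines, as the log2 level at 5000 nM minus that at 0 nM (y axis). Each grey point is 1 line and the black diamond and bars are the mean ± SD. DHRS2 has the largest mean, 4.46, and NMI the lowest, -2.65, and a few lines lie near 0 for each gene.

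Genes of cell division fell together. Of 28 DNA replication genes 22 fell, 0 rose and 6 did neither, also 22 when adjusted over the list alone. Among them were MCM5 of the replicative helicase (-2.08 ± 0.96), POLE2 (-1.85 ± 1.04) and CTPS1, which makes CTP (-1.72 ± 0.80). Of 26 mitosis genes 23 fell, such as AURKA (-1.73 ± 1.21), PLK1 (-1.72 ± 1.28), UBE2C (-1.65 ± 1.29) and AURKB (-1.63 ± 1.37). Of 18 genes of homologous recombination and Fanconi repair 10 fell, CHEK1 (-1.52 ± 0.93), BRCA1 (-1.24 ± 1.08), BARD1 (-1.19 ± 0.86) and RAD54L (-1.17 ± 0.91) the most. The mean of the replication list was lower in 56 of 59 lines and that of the mitosis list in 49. Their adjusted p from camera were 2e-10, 1.9e-06 and 0.00083 in this order, and adjusted p = 0.40, 0.58 and 0.40 with an estimated correlation. For every list, dose and time the counts adjusted over the list alone equalled those over all genes.

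Among genes of growth and synthesis, the lists of ribosome biogenesis and of polyamine and nucleotide synthesis passed camera. In the ribosome biogenesis list 7 of 18 fell, with UTP20 at -1.87 ± 0.84, NIP7 at -1.07 ± 0.68 and RRS1 at -0.79 ± 0.65 (adjusted p = 5.6e-05, adjusted p = 0.40 with an estimated correlation). NOP16 fell as well (-0.96), but the mean over its probe sets was -0.58 and did not pass. In polyamine and nucleotide synthesis 9 of 18 fell, SRM, which makes spermidine (-1.39 ± 0.77), among them, while 2 rose, SAT1, which breaks polyamines down (1.70 ± 0.91), and ODC1 (0.94), with adjusted p = 0.00022, and adjusted p = 0.40 with an estimated correlation. Of 17 cytosolic ribosomal proteins none passed, and the list mean was 0.00 with a median over members of -0.01. In oxidative phosphorylation 3 of 22 fell, NDUFS3 (-0.72 ± 0.36), CYC1 (-0.67 ± 0.36) and NDUFA9 (-0.64 ± 0.41), none rose, and the list mean was -0.03, its median 0.02 and its test pointing up (adjusted p = 0.92). Of 12 reference genes none passed: the list mean was 0.02 and the median -0.01, and the largest value was 0.48 ± 0.35 for SDHA.

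CDKN1A (202284_s_at) rose 3.57-fold (1.83 ± 1.22) in 57 of 59 lines. With it rose CDKN1C (1.35 ± 1.43), GADD45B (1.34 ± 1.05), BTG1 (1.13 ± 0.66) and 2 more of the 14 CDK inhibitors and growth arrest genes, while CDKN1B, the CDK inhibitor p27, fell (-0.71). The list passed (adjusted p = 0.027, adjusted p = 0.33 with an estimated correlation), but not without the 12 line names (adjusted p = 0.053). Of 17 p53 targets 4 rose and 3 fell: TNFRSF10B, a receptor of the death ligand TRAIL, rose (1.04 ± 1.25) and TP53I3 (-1.18 ± 0.99) and FAS (-1.15 ± 1.10) fell. That list had a mean of 0.05, a median of -0.11 and a test pointing down, and did not pass (adjusted p = 0.92).

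Among apoptosis genes, BID fell (-1.86 ± 0.80) and BNIP3L (0.83 ± 0.69), BIK (0.65 ± 0.85) and BCL2L11 (0.60 ± 0.57) rose, of 11 pro-apoptotic BCL2 family genes. The rise of BCL2L11 did not pass with quantile normalization (0.53) or over the mean of its probe sets (0.48). Of 9 anti-apoptotic genes CFLAR (-1.65 ± 0.94), BIRC5 (-1.28 ± 1.22) and BCL2L2 (-0.61 ± 0.57) fell, the last not with quantile normalization (-0.57). Of 10 death receptors and ligands 2 rose and 3 fell, FAS and TNFRSF1A (-0.74 ± 0.95) among those that fell. None of these 3 lists passed (adjusted p = 0.50, 0.092 and 0.48).

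Histone and chromatin genes moved in both directions. Of the 13 genes in the list named for replication-independent and linker histones 7 rose and 0 fell. The histone cluster genes H1-2, H2BC21 (2.04 ± 1.40), H2BC5 (1.80 ± 1.14) and H2AC6 (1.54 ± 1.24) rose the most, and the list mean was higher in 57 of 59 lines (adjusted p = 0.054). Of 9 measured histone deacetylases HDAC5 (1.22 ± 0.75) and HDAC3 (216326_s_at, 1.05 ± 0.43) rose. HDAC1 had a change of 0.28 ± 0.28, HDAC6 of 0.29 ± 0.54 and HDAC2 of -0.06 ± 0.25, and none of the 3 passed. Of 12 histone acetyltransferases 5 fell, with KAT6B at -1.08 ± 0.62, KAT2A at -0.87 ± 0.45 and KAT7 at -0.75 ± 0.45 (adjusted p = 0.0037, adjusted p = 0.36 with an estimated correlation). CREBBP, counted among the 5, did not pass over the mean of its probe sets (-0.50). Of 13 bromodomain and elongation factors HEXIM1, an inhibitor of P-TEFb, rose (0.62 ± 0.63). ELL2 (0.95) rose too, but not over the mean of its probe sets (0.49), and CCNT2 (-0.59) fell, but not with quantile normalization (-0.55).

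**Figure D3:**
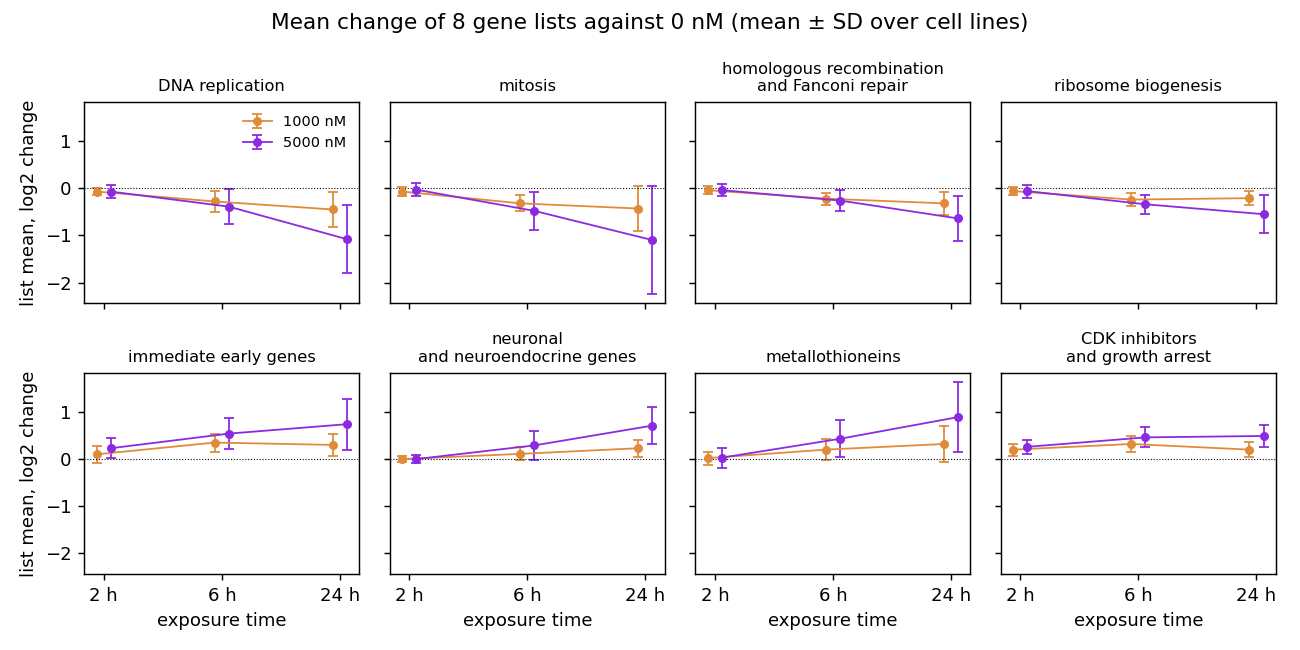
Mean log2 change against 0 nM of 8 gene lists (y axis) by exposure time (x axis) and dose (colour). Points are the mean over cell lines of each line's list mean and bars are ± SD. At 5000 nM the DNA replication list runs from -0.07 at 2 h to -1.08 at 24 h, and the metallothionein list from 0.03 to 0.89.

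Of the stress and signalling lists the metallothioneins and the immediate early genes passed camera with the preset correlation, and the others did not. Of 8 metallothioneins, small zinc-binding proteins, 6 rose and 0 fell, with MT1X at 1.35 ± 1.00, MT1F at 1.33 ± 1.05 and MT1G at 1.22 ± 1.06 (adjusted p = 0.0054, adjusted p = 0.41 with an estimated correlation). Of the 22 immediate early genes 14 rose, FOS (2.01 ± 1.10), ATF3 (1.84 ± 1.33) and DUSP1 (1.62 ± 1.27) the most, and FOSL1 fell (-1.99 ± 1.66), with adjusted p = 0.00022, and adjusted p = 0.40 with an estimated correlation. In the thioredoxin and NRF2 antioxidant list 5 of 15 rose, such as the thioredoxin inhibitor TXNIP (1.78 ± 1.16), GLRX (1.26 ± 0.81) and HMOX1 (1.18 ± 1.30), and 3 fell (adjusted p = 0.066). Of 15 heat shock genes HSPA2 (1.17 ± 1.18) and DNAJB1 (0.79 ± 0.58) rose, and HSPH1 (-1.08 ± 0.69) and HSPE1 (-0.94 ± 0.53) fell (adjusted p = 0.48). Of 19 genes of the unfolded protein and integrated stress response 6 rose and 2 fell, the latter XBP1 (-1.44 ± 0.77) and TRIB3 (-1.01 ± 0.88), with adjusted p = 0.48. Of 19 genes of hypoxia response and glycolysis 6 rose, SLC2A3, a glucose transporter (1.93 ± 1.42), ALDOC (1.80 ± 1.65) and NDRG1 (1.43 ± 1.11) the most, and none fell (adjusted p = 0.11). Of 14 cholesterol genes only INSIG1 passed at this time (0.80 ± 0.92; adjusted p = 0.53 for the list).

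Of the lists of differentiated cell types the neuronal one passed camera. Of 25 neuronal and neuroendocrine genes 12 rose and 0 fell, SYT11 (2.16 ± 1.24), VGF (1.79 ± 1.59), SCG2 (1.47 ± 1.52) and the microtubule protein tau (MAPT, 1.37 ± 0.97) the most. The list mean was higher in 56 of 59 lines (adjusted p = 9.3e-05, adjusted p = 0.33 with an estimated correlation). Of 18 genes of MHC presentation 7 rose and 3 fell: HLA-DMB (1.78 ± 1.11) and HLA-DMA (1.22 ± 0.94), which load class II molecules with peptide, rose, and the immunoproteasome subunit PSMB8 (-1.17 ± 1.00) fell (adjusted p = 0.13). ERAP1 fell (-1.03), but not over the mean of its probe sets (-0.45). Of 21 interferon-stimulated genes 4 rose, IFIT1 (1.29 ± 1.43) and ISG15 (0.90 ± 1.12) the most, and 4 fell, IFI35 (-1.06 ± 0.85) and IFIT3 (-0.91 ± 0.97) the most (adjusted p = 0.48). Of 17 epithelial genes CDS1 (1.46 ± 1.29) and ELF3 (1.03 ± 1.21) rose and ESRP1 (-0.59 ± 1.58) fell, the last not with quantile normalization (-0.58), and the list had adjusted p = 0.53. Of 18 mesenchymal genes FN1 (1.18 ± 1.54) and COL1A1 (1.10 ± 1.55) rose and ZEB2 (-0.89 ± 1.13) and AXL (-0.88 ± 1.67) fell (adjusted p = 0.92). The mean over the probe sets of COL1A1 was 0.24 and did not pass. Of 15 receptor kinases and HSP90 clients CDK4 (-1.0 ± 0.48), AKT1 (-0.66 ± 0.42) and ERBB2 (-0.91 ± 0.69) fell, ERBB2 not over the mean of its probe sets (-0.52), with adjusted p = 0.48 for the list. None of 13 cancer-testis antigens passed, MAGEB2 having the largest value (0.49 ± 0.99; adjusted p = 0.50 for the list).

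In all, 2520 genes, 21.1% of those tested, passed at 5000 nM and 24 h, 1265 higher and 1255 lower. Without the 12 line names 2826 passed, and 2503 genes were called in the same direction both times. With the lowest 40% of genes left out 1068 were higher and 1213 lower. Camera called 10 lists, and up to 14 when the signs of the changes were reversed in random lines. The 24 h arrays at 5000 nM labelled BT-549, HCT-116, M14, NCI-H226, SK-MEL-5 and SK-OV-3 differed from their untreated arrays by a root mean square of 0.254, 0.209, 0.263, 0.205, 0.216 and 0.476, against 0.637 or more in the 47 lines outside the 12.

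The next comparisons ask what the lower dose changed. At 1000 nM and 6 h RGL1 rose 3.63-fold (1.86 ± 0.82, n = 58), HEY1 2.86-fold (1.51 ± 0.95) and TUFT1 2.79-fold (1.48 ± 0.71), and WDR19 (1.34) and FAM117A (1.32) rose as well. PRDM10 fell 3.35-fold (-1.75 ± 0.68), MEPCE 3.28-fold (-1.72 ± 0.44) and KEAP1 2.85-fold (-1.51 ± 0.52), with CASD1 (-1.47) and GINS3 (-1.45). By 24 h DHRS2 had risen 4.48-fold (2.16 ± 2.06, n = 59), SERPINI1 2.82-fold (1.5 ± 1.05) and ABAT 2.69-fold (1.43 ± 1.08), with ARG2 (1.26) and the postsynaptic protein NRGN (1.23). ADI1 (-1.66 ± 0.76), PMF1 (-1.41 ± 0.60), LANCL2 (-1.37 ± 0.52), MEPCE (-1.34 ± 0.51) and ATF5 (-1.27 ± 0.50) fell. CDKN1A rose 1.94-fold at 6 h (0.95 ± 0.62) and 1.83-fold at 24 h (0.88 ± 0.76), and had a change of 0.22 ± 0.39 at 2 h that did not pass. HDAC3 had changes of 0.15 ± 0.18, 0.45 ± 0.19 and 0.20 ± 0.21 at 2, 6 and 24 h, none of which reached 1.5-fold, and HDAC1, HDAC2 and HDAC6 stayed between -0.19 and 0.18.

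Some genes had moved at 1000 nM by 2 h. PLEKHF1 rose 2.00-fold (1.00 ± 0.55, n = 59), DDIT4 1.90-fold (0.92 ± 0.66), BCL6 1.84-fold (0.88 ± 0.71) and OSR2 1.82-fold (0.86 ± 0.51), while KLF11 fell 1.82-fold (-0.86 ± 0.44), LIF 1.76-fold (-0.81 ± 0.61), NFKBIA 1.70-fold (-0.77 ± 0.33) and TRIM13 1.64-fold (-0.72 ± 0.26). NFKBIA and TRIM13 were lower in all 59 lines. VAMP1 rose in all 59 lines (0.87 ± 0.41) and ZBTB1 fell in 57 (-0.70 ± 0.43), but over the mean of their probe sets the values were 0.41 and -0.48 and did not pass.

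Of the gene lists at 1000 nM, the histone acetyltransferases had 5 members that fell at 6 h and 0 that rose, KAT7 (-0.85 ± 0.34) among them, with a list mean of -0.50 ± 0.14 (adjusted p = 9.9e-05, adjusted p = 0.053 with an estimated correlation). Of the 22 immediate early genes 8 rose and 1 fell at 6 h, FOSL1 (-0.84 ± 0.70), and the list mean was higher in all 58 lines (adjusted p = 0.00043, adjusted p = 0.18 with an estimated correlation). At 24 h 8 of 28 DNA replication genes fell, MCM5 (-0.86 ± 0.59), TYMS (-0.84 ± 0.57) and POLE2 (-0.62 ± 0.56) among them (adjusted p = 3.4e-10, adjusted p = 0.37 with an estimated correlation). Of 26 mitosis genes 5 fell, such as AURKA (-0.66 ± 0.52), and of 18 repair genes 4 fell, such as RAD54L (-0.59 ± 0.51), with adjusted p = 6.8e-07 and 9.6e-05, and adjusted p = 0.50 and 0.34 with an estimated correlation. Of 25 neuronal genes 5 rose at 24 h, MAPT (0.74 ± 0.66) among them, and of 19 hypoxia and glycolysis genes 4 rose, among them NDRG1 (0.78 ± 0.66), with adjusted p = 0.0083 and 0.0067, and adjusted p = 0.34 for both with an estimated correlation. Camera called 10, 10 and 12 lists at 2, 6 and 24 h, and 0 at each time with an estimated correlation.

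At 1000 nM 45 genes passed at 2 h (31 higher, 14 lower), 663 at 6 h (358 higher, 305 lower) and 421 at 24 h (243 higher, 178 lower). With each array median-centred the balance turned, to 309 higher and 365 lower at 6 h and 214 and 219 at 24 h, and without the line as a block it was 147 and 168 at 24 h. Without the 12 line names 40, 726 and 553 passed, and camera called 6 lists at 2 h, without the immediate early list (adjusted p = 0.24).

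The doses were then set against each other within lines. At 2 h FOS alone passed between 5000 and 1000 nM, 1.66-fold higher at 5000 nM (0.73 ± 0.45, adjusted p = 1.2e-15) in 57 of 59 lines, while 1482 genes had an unadjusted p under 0.05 from limma. At 6 h CRISPLD2 was 3.05-fold higher at 5000 nM (1.61 ± 0.94, n = 57), DHRS2 2.49-fold (1.31 ± 0.89), FOS 2.15-fold (1.10 ± 0.64), RGL1 2.05-fold (1.03 ± 0.61) and BAIAP2 1.99-fold (0.99 ± 0.44). TGIF1, a repressor of TGF-beta signalling, was 1.93-fold lower (-0.95 ± 0.52), with BHLHE40 (-0.80 ± 0.64). HMGA2 (-0.79) was lower too but not without the 12 line names (-0.58), and ZMYND8 and SMAD1 (-0.76 each) were lower but not over the mean of their probe sets (-0.42 each). By 24 h the gap between doses was 4.92-fold for DHRS2 (2.30 ± 1.65, n = 59), 4.68-fold for CRISPLD2 (2.23 ± 1.27), 3.97-fold for HPCAL4 (1.99 ± 1.15), 3.87-fold for ABAT (1.95 ± 1.12) and 3.76-fold for the histone gene H2BC21 (1.91 ± 1.36). In the other direction HMGA2 was 4.20-fold lower at the higher dose (-2.07 ± 1.43), TYMS 3.20-fold (-1.68 ± 1.11), NSMAF 3.16-fold (-1.66 ± 0.80), NRP1, a receptor of semaphorins and VEGF, 3.08-fold (-1.62 ± 1.30) and TFPI, an inhibitor of blood clotting, 3.01-fold (-1.59 ± 1.5).

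Between the doses 1, 77 and 1083 genes passed at 2, 6 and 24 h, of which 53 and 526 were higher at 5000 nM at the last 2 times. At 24 h the remaining 557 were lower, and the balance turned, with 572 of 1121 higher with quantile normalization and 598 of 1094 with median centring. The counts were 1, 52 and 1305 without the 12 line names. At 6 h 351 genes rose at both doses and 300 fell at both, where independent lists would share 24.7 and 17.2, and at 24 h 231 and 173 did, against 25.7 and 18.7. At 2 h 31 rose and 13 fell at both doses, against 0.158 and 0.0398, and 0 genes went in opposite directions at any time. The doses share their untreated arrays, so part of this overlap may come from these. The mean changes at both doses had r = 0.95, 0.96 and 0.86 over genes at 2, 6 and 24 h and covariances of 0.0134, 0.102 and 0.108. With each dose taken from a different random part of the lines r was 0.85, 0.93 and 0.82 and the covariance 0.0129, 0.101 and 0.107, and simulated unchanged groups gave r of 0.53, 0.66 and 0.59 and covariances of 6e-04, 0.0013 and 0.0019. These correlations are over genes, which are not independent replicates. The slope of the 1000 nM change on the 5000 nM change was 0.76 at 2 h, 0.67 at 6 h and 0.40 at 24 h.

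A further set of comparisons asks whether the change itself differed between times. At 5000 nM the change of RGL1 was 5.72-fold larger at 6 h than at 2 h (2.52 ± 1.13, n = 57), that of DHRS2 4.72-fold (2.24 ± 1.94), CRISPLD2 4.10-fold (2.04 ± 1.53), the matricellular protein CCN2 3.86-fold (1.95 ± 1.69) and ABAT 3.65-fold (1.87 ± 1.36). Lower at 6 h than at 2 h were JADE2 (-1.61 ± 0.73), PRDM10 (-1.56 ± 1.11), KEAP1 (-1.49 ± 0.77), ZMYND8 (-1.45 ± 0.86) and lamin B1 (LMNB1, -1.43 ± 0.66), the last in all 57 lines. From 6 to 24 h the change went up for DKK1, an inhibitor of Wnt signalling (2.03 ± 2.68, n = 57), H1-2 (1.85 ± 2.20), DHRS2 (1.82 ± 2.86), C11orf71 (1.81 ± 1.59) and ENPP2 (1.78 ± 2.24), and down for TYMS (-1.82 ± 1.79), SERPINH1 (-1.81 ± 2.00), ADI1 (-1.75 ± 1.59), NMI (-1.65 ± 1.62) and the immunoproteasome subunit PSMB10 (-1.60 ± 1.60). For several of these the SD over lines was larger than the mean. The means and SDs from 6 to 24 h include the labels BT-549, HCT-116, M14, NCI-H226 and SK-MEL-5. Under these labels the 6 h change at 5000 nM correlated best over genes with the mean 24 h change of lines without doubtful arrays. The 24 h change correlated best with their mean 2 h change. Without all 12 names 0 of 370 values of named genes reversed and 16 lost their call, over all comparisons. How much these labels alone moved the mean and SD of each gene was not tested.

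At 1000 nM RGL1 went up from 2 to 6 h (1.64 ± 1.19, n = 58) and down again from 6 to 24 h (-0.95 ± 0.84), and PRDM10 went down (-1.41 ± 1.13) and then up (1.27 ± 0.69). ABAT (1.18 ± 1.02), CCN2 (1.16 ± 0.90), SSBP2 (1.16 ± 0.92) and GRK5 (1.13 ± 0.80) also went up by 6 h, and CASD1 (-1.21 ± 0.76), KAT6B (-1.14 ± 0.79), KEAP1 (-1.13 ± 0.75) and MEPCE (-1.09 ± 0.75) down. From 6 to 24 h CYP1B1 (1.08 ± 1.21), ZMYND8 (1.03 ± 0.57), DKK1 (1.00 ± 1.51) and ZC3H4 (0.93 ± 0.55) went up and ADI1 (-1.13 ± 1.17), WDR19 (-0.88 ± 0.57) and TUFT1 (-0.88 ± 0.59) down. SNN went down as well (-0.92), but not over the mean of its probe sets (-0.58).

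The number of genes whose change differed was 838 between 6 and 2 h at 5000 nM (462 up, 376 down), 760 between 24 and 6 h (316 up, 444 down), and 242 and 132 at 1000 nM. These were 936, 1320, 390 and 281 without the 12 line names. Fitted without the line as a block they were 553 (244 up, 309 down), 466, 113 (32 up, 81 down, against 140 and 102 with it) and 65, and with each array median-centred 391 went up and 366 down between 24 and 6 h at 5000 nM. Of the genes called at 5000 nM, 637 rose and 484 fell at both 6 and 24 h (independent lists would share 87.2 and 70.6), and 1 changed sides.

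Untreated cells were compared at 24 and 2 h as the background of these changes. DDIT4 was 2.27-fold higher at 24 h (1.18 ± 0.99, n = 59, adjusted p = 2.3e-10), and FAM200C (0.74 ± 0.57), ZNF322 (0.72 ± 0.71) and WDR5B (0.68 ± 0.66) were higher. TMT1A was too (0.64), but not over the mean of its probe sets (0.26). ATF3 (-0.90 ± 1.20), MAFF (-0.84 ± 1.35), KLF11 (-0.80 ± 0.81), PPP1R15A (-0.78 ± 0.79) and CCN2 (-0.75 ± 1.72, adjusted p = 0.012) were lower. In all 17 genes passed, 7 higher and 10 lower, and 45 without the 12 line names. Without M14, SK-MEL-5 or T-47D alone 26, 26 and 27 passed, and 6 passed with the line left out as a block, 5 higher and 1 lower. With each array median-centred 5 were higher and 16 lower.

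**Figure D4:**
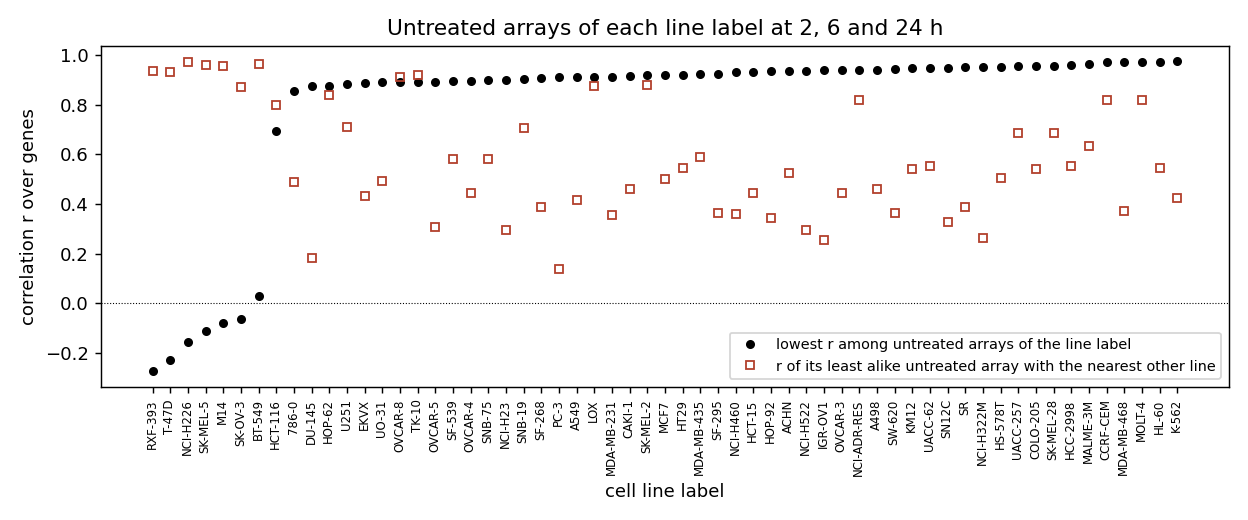
Correlation over genes (y axis) between untreated arrays, for each of the 59 cell line labels (x axis), ordered by the black points. Black points are the lowest correlation among the 2, 6 and 24 h arrays of a label, and red squares are that of its least alike array with the nearest array of another line. For 8 labels the black point lies at 0.692 or lower and the red square above it, and for the 47 lines outside the 12 named ones the black point lies at 0.853 or higher.

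Tissues of origin were compared at 5000 nM and 24 h, in 59 lines. The 10 genes with the smallest p in limma's F-test over the 9 tissues each stood apart in the 5 leukemia lines. Blood cell genes with lower values there were PTPN7 (-2.97 ± 1.01, F = 25, adjusted p = 1.6e-11), CD53 (-1.46 ± 0.53, adjusted p = 2.9e-09), the inhibitory receptor LAIR1 (-2.18 ± 1.14, adjusted p = 3.6e-09), PTPRCAP (-2.57 ± 1.65, adjusted p = 5.4e-08), the adaptor SLA (-2.33 ± 1.57), the lymphoid factor IKZF1 (-2.17 ± 1.40) and LMO2 (-2.34 ± 1.39), with PSD4 (-1.37 ± 0.36). The cytoskeletal genes CAMSAP2 (2.38 ± 1.17, adjusted p = 6e-09) and vinculin (VCL, 2.51 ± 1.26, adjusted p = 1.1e-05) were higher in leukemia lines, while CAMSAP2 lay between -0.42 and -0.11 in the other 8 tissues and VCL between 0.16 and 0.58. In untreated 24 h arrays PTPN7, CD53, LAIR1, PTPRCAP, SLA, IKZF1 and LMO2 stood at 8.17 to 10.52 in leukemia lines. In the other lines these genes stood at 4.10 to 5.03 and had little room to fall. The F-test called 637 genes, 5.32%. It called 1393 without the 12 line names, 162 without the leukemia lines, 868 without both the leukemia lines and the 12 names, and 219 at 1000 nM. The prostate group holds 2 lines.

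Leukemia lines, which grow in suspension, were also set against the other 54. IER3 changed by 4.82 ± 2.17 in leukemia and by 1.12 ± 1.25 elsewhere (adjusted p = 1.2e-05), TNFRSF10B by 3.95 ± 1.81 and 0.77 ± 0.77 (adjusted p = 4.1e-08), SPP1, the secreted protein osteopontin, by 3.89 ± 2.78 and 0.72 ± 1.11 (adjusted p = 0.00013), the tetraspanin CD9 by 3.72 ± 2.20 and 0.57 ± 0.67 (adjusted p = 3.2e-08) and the kinase SGK1 by 3.70 ± 0.66 and 0.82 ± 1.07 (adjusted p = 1.6e-05). PTPN7, PTPRCAP, LMO2, LAIR1 and SLA differed in the other direction, by -2.98, -2.69, -2.56, -2.43 and -2.42. CD9 stood at 4.79 in untreated leukemia lines and at 11.15 elsewhere, and PTPN7 at 8.69 and 4.37. For CDKN1A the difference, 1.44, did not pass (adjusted p = 0.092). The test called 579 genes, 260 higher and 319 lower in leukemia, and 658 without the 12 line names, 309 higher and 349 lower. Leaving out CCRF-CEM gave 376, leaving out SR 756, and the test called 165 at 1000 nM, 149 of them higher. With each array median-centred 193 were higher and 535 lower, and with the lowest 40% of genes left out 230 and 158.

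Markers of each tissue of origin were followed in lines of that tissue at 5000 nM and 24 h. In 9 melanoma lines 6 of 12 melanocyte genes fell and 0 rose: RAB38 (-1.52, adjusted p = 0.0093), the lineage factor SOX10 (-1.45, adjusted p = 0.021), SLC45A2 (-1.43, adjusted p = 0.046), MLANA (-1.34, adjusted p = 0.036), RAB27A (-1.33, adjusted p = 0.0085) and tyrosinase (TYR, -1.32, adjusted p = 0.0099). PMEL had 0.70 and did not pass. The list mean was -0.94 ± 1.00 from an untreated level of 7.98, was lower in 7 of 9 lines, and had adjusted p = 0.0033, and adjusted p = 0.55 with an estimated correlation. In the untreated 24 h arrays labelled LOX, M14, SK-MEL-2 and SK-MEL-5, 4 of the 12 names, TYR stood at 4.29, 4.11, 4.43 and 4.71, against 11.04 to 13.03 in the other 5 melanoma lines. EPCAM, of the epithelial list, stood at 12.22, 3.57, 12.03 and 6.57 in the same order, against 3.92 to 4.21 in the other 5. In these 5 the list mean was -1.70, and the changes were -2.43 for RAB38, -2.52 for SOX10, -2.54 for SLC45A2, -2.17 for MLANA, -1.92 for RAB27A and -2.16 for TYR. In 5 leukemia lines IKZF1 (-2.17, adjusted p = 0.023) and CD53 (-1.46, adjusted p = 0.0056) of 16 haematopoietic genes fell and 0 rose, and the list mean was -0.88 ± 0.45, lower in 5 of 5 lines (adjusted p = 0.0033, adjusted p = 0.55 with an estimated correlation).

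**Figure D5:**
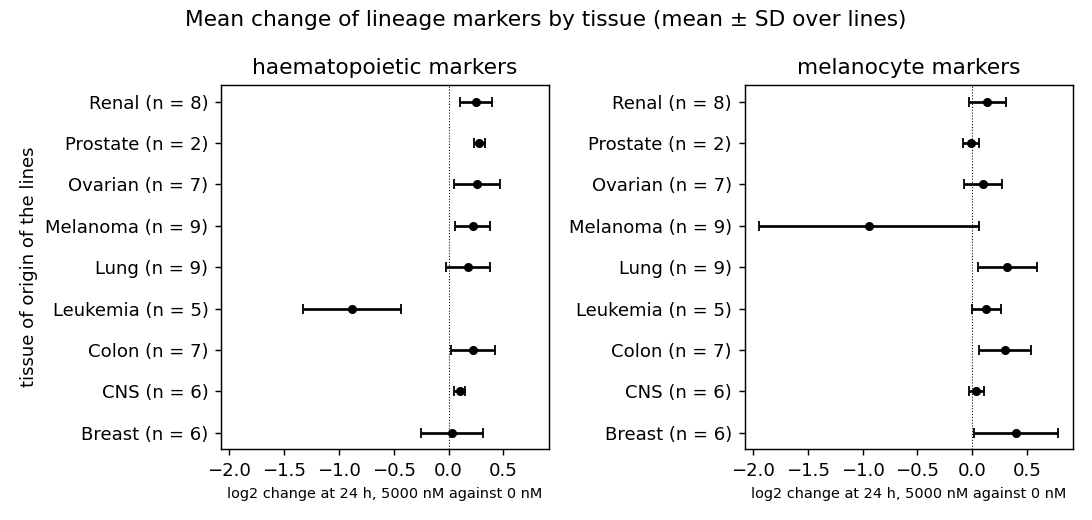
Mean log2 change at 24 h, 5000 nM against 0 nM (x axis), of haematopoietic and melanocyte markers in lines of each tissue of origin (y axis). Points are the mean over lines and bars are ± SD. The haematopoietic mean is -0.88 in leukemia lines and the melanocyte mean -0.94 in melanoma lines, and all the other tissues lie between -0.01 and 0.40. The untreated haematopoietic level was 8.90 in leukemia and 5.05 in the other lines. The melanocyte level was 7.98 in melanoma and 5.31 in the other lines. The other tissues thus had less room to fall, and the contrast cannot be told apart from this.

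In 8 renal lines PAX8 (-1.26, adjusted p = 0.00032) and PAX2 (-1.09, adjusted p = 0.0049), transcription factors of the kidney tubule, fell, in 8 and 7 of the lines, while the list of 9 had a mean of -0.27 ± 0.24 and did not pass (adjusted p = 0.56). The kidney list had a like mean in the 7 ovarian lines, -0.24 ± 0.49. Without RXF-393 and TK-10, renal labels among the 12 names, the changes were -1.22 for PAX8 and -1.14 for PAX2. In 6 CNS lines OLIG2 rose (1.27, adjusted p = 0.00056) and the glutamate transporter SLC1A3 fell (-0.67, adjusted p = 0.013), with a list mean of -0.05 ± 0.22 (adjusted p = 0.56). None of 11 colon markers passed in 7 colon lines (mean -0.21 ± 0.43, adjusted p = 0.55), nor any of 10 luminal markers in 6 breast lines, where the mean was 0.12 ± 1.26, 5 of 6 lines were lower and the test pointed down (adjusted p = 0.76). In the 4 breast lines outside the 12 names, which leave out BT-549 and T-47D, that mean was -0.43.

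Over all 59 lines these marker lists did not pass. Among 12 melanocyte genes PMEL (1.76 ± 1.52) and GPNMB (0.76 ± 1.05) rose and RAB27A fell (-1.18 ± 0.70), with a mean of 0.03, a median of -0.16 and a test pointing down (adjusted p = 0.90). Among 16 haematopoietic genes CORO1A rose (2.02 ± 1.28) and so did RAC2 (0.60), the latter not over the mean of its probe sets (0.38), with a mean of 0.10 and a median of -0.07 (adjusted p = 0.92). KRT20 rose among 11 colon genes (0.59), but not with quantile normalization (0.58), with adjusted p = 1.0 for the list. NES rose among 11 glial genes (0.77 ± 1.08, adjusted p = 0.92 for the list), none of 9 kidney genes passed (adjusted p = 0.92), and XBP1 fell among 10 luminal genes (adjusted p = 0.48). The mean and median of the colon list were 0.02 and -0.01, and those of the glial list 0.03 and -0.02.

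The size of the response was given per line as the root mean square change over all genes. Its median over lines was 0.231, 0.393 and 0.406 log2 units at 2, 6 and 24 h at 1000 nM, and 0.246, 0.507 and 0.749 at 5000 nM. At 5000 nM and 24 h the tissue medians ran from 0.690 in CNS and 0.693 in breast lines to 0.833 in melanoma and 0.839 in ovarian lines, and single lines from 0.205 (NCI-H226) to 1.496 (T-47D), both among the 12 names. The treated and untreated T-47D arrays at 24 h correlated at -0.21. No difference between tissues passed at any dose and time in a permutation test of the Kruskal-Wallis statistic (100000 resamples), with p from 0.017 (1000 nM, 24 h) to 0.99, and adjusted p of 0.10 to 0.99 over the 6 tests. At 5000 nM and 24 h single lines ran from 0.637 to 1.137 without the 12 names, and the test gave p = 0.094 in place of 0.63 (adjusted p = 0.28 and 0.99).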

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

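All the tests of explanations and the regroupings of lines in this part were chosen after the results they measure were seen.

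In 11 of 48 groups of lines of 1 tissue at 1 dose and time, 1 line stood far from the nearest of the others in response size, where chance gives about 1 in 20 groups, or 2.4. At 1000 nM these were NCI-H226 at 2 h (0.408 log2 units), A549 at 6 h (0.201), RXF-393 at 6 h (0.177) and TK-10 at 24 h (0.559). At 5000 nM they were HCT-116 (0.651), NCI-H226 (0.513) and RXF-393 (1.244) at 2 h, HCT-116 (0.858), SK-OV-3 (0.761) and RXF-393 (1.253) at 6 h, and NCI-H226 at 24 h (0.205). All but the value of A549, 10 in number, lie in the 12 line names with arrays nearest to another line.

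The first pattern is that the untreated arrays of 8 labels differed between times. The lowest correlation among the 3 untreated arrays of a label was -0.273 for RXF-393, -0.228 for T-47D, -0.155 for NCI-H226, -0.111 for SK-MEL-5, -0.079 for M14, -0.065 for SK-OV-3, 0.029 for BT-549 and 0.692 for HCT-116, and 0.853 or higher in the 47 lines outside the 12. Drift of the cells over the time in culture is argued against, since 7 of the 8 least alike arrays correlated with an array of another line at 0.853 or more (the 24 h array of NCI-H226 with SK-MEL-5 at 2 h at 0.971, that of SK-MEL-5 with RXF-393 at 2 h at 0.960), and a mixed sample is argued against by a median share of the own profile of 0.9%, though HCT-116 had 27.2%. A mislabelled sample may explain it: for 7 of the 8 the separately made 1000 nM array of that time was nearest to the same other line as the untreated one, the exception being RXF-393 at 6 h (BT-549 and HCT-116). No biological explanation other than this drift was tested, and the other 4 of the 12 names, OVCAR-8 and TK-10, LOX and SK-MEL-2, were alike at all times and close to another label throughout. The least alike untreated arrays of TK-10, LOX and SK-MEL-2 correlated at 0.919, 0.875 and 0.880 with OVCAR-8, SK-MEL-2 and BT-549. Labels that hold the same cells would count 1 line more than 1 time, perhaps under a tissue not its own, which was not tested.

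The second pattern is the small 24 h change at 5000 nM under 6 labels, BT-549 (0.254), HCT-116 (0.209), M14 (0.263), NCI-H226 (0.205), SK-MEL-5 (0.216) and SK-OV-3 (0.476), against a median of 0.751 in the 47 other lines. That the cells on these arrays respond little to vorinostat is argued against only as far as they can be matched to arrays of other times or labels. The 6 h arrays of the same label could not decide it for the 6 as a set. The untreated 6 and 24 h arrays were alike in 1 of the 6, HCT-116. Its 6 h change was 0.858, where the lowest of the 47 lines was 0.400 at 6 h and 0.637 at 24 h. The untreated 24 h arrays of BT-549, M14, NCI-H226 and SK-OV-3 correlated at 0.965, 0.954, 0.971 and 0.869 with 2 h arrays labelled T-47D, NCI-H226, SK-MEL-5 and M14. Under those labels the untreated 2 and 6 h arrays were alike, and the 6 h changes were 0.894, 0.681, 0.687 and 0.897. The 24 h array of SK-MEL-5 correlated at 0.960 with RXF-393 at 2 h. The 24 h change of RXF-393 was 0.65, where the lowest of the 47 lines was 0.637. Arrays of a shorter exposure under the 24 h label may explain the small change. In 6 of the 6 labels the 24 h change correlated best over genes with the mean 2 h change of the 47 lines. In 47 of 47 other lines it was nearest to the 24 h mean. But the values were low, in 5 labels r = 0.28 to 0.45 with the 2 h mean against 0.08 to 0.17 with the 24 h mean. SK-OV-3 had 0.14, 0.05 and 0.02 with the 2, 6 and 24 h means and resembled none, so its case stays open. In the 5 labels besides SK-OV-3 the 2 h change was nearest to the 6 h mean and the 6 h change to the 24 h mean, so these labels may be displaced by 1 time, but no source used here settles it, and T-47D had the same shift at 2 and 6 h (r = 0.75 and 0.71) with a large 24 h change (1.496) nearest to the 24 h mean (r = 0.52).

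The third pattern is the difference of the leukemia lines, 579 genes at 24 h, PTPN7 and LMO2 among those lower and CD9 and IER3 among those higher. Genes near the lower end of the array scale may account for part of the lower genes. Of the 319 genes lower in leukemia 53.6% were among the lowest 40% of genes in the other lines, where they had little room to fall. Of the 260 higher genes 26.2% were among the lowest 40% in leukemia lines. The boundary holds 40% of all genes below it, by their mean over all arrays. The lower genes thus lay above that share and the higher genes below it. Neither share decides it, so the explanation cannot be told apart from a difference of tissue for these genes. A biological difference of blood-derived lines stays open and untested. Chance is argued against but not excluded. Of 100 regroupings of the lines 1, the real one, gave as many genes, and the highest of the others gave 304. That share is the lowest that 100 regroupings can give.

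The change differed between times in 242 genes (6 against 2 h) and 132 genes (24 against 6 h) at 1000 nM, and in 838 and 760 genes at 5000 nM. Tissues differed in 637 genes. In data outside the comparisons, 181 of 2108 probe sets with no gene name here passed at 5000 nM and 24 h, 112 higher and 69 lower, against 0 in the untreated cells between 24 and 2 h (limma with the same thresholds).

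In 100 regroupings, the real one included, the signs of the changes were reversed in random lines or the tissue names moved between lines. Only the real one (1 of 100) gave as many genes in each of the 16 gene counts, which argues against chance. It is the lowest share that 100 regroupings can give, and the 16 were not adjusted, so chance is not excluded. The highest of the others was 488 for the 2520 genes at 5000 nM and 24 h, 5 for the 421 at 1000 nM and 24 h, 37 for the 1083 between doses at 24 h, 117 for the 760 between 24 and 6 h at 5000 nM, 80 for the 637 of the tissue test, and 0 for the other 10 counts. For the gene lists called with the preset correlation, 2 of 100 regroupings gave as many as the 10 at 1000 nM and 2 h (highest other 10). This was 1 of 6 list counts tested with no adjustment, and 0 lists were called there with an estimated correlation, so chance is not excluded. Nor can chance be excluded for the other 5 counts of lists: 11 of 100 gave as many as the 10 at 1000 nM and 6 h (highest other 14), 6 as many as the 12 at 24 h (15), 11 as many as the 9 at 5000 nM and 2 h (11), 5 as many as the 13 at 6 h (14) and 18 as many as the 10 at 24 h (14).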

How the results depend on the processing

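The alternatives without the 12 line names, without leukemia lines together with the 12, and without each leukemia line were chosen after the results were seen, and all others before. The total counts stayed within 1.5 times of the main value under the mean of all probe sets (22 values), with the lowest 40% of genes left out (16), with quantile normalization (22) or median centring (16), with eBayes without trend (16), the Wilcoxon signed-rank test (14), 1 fit of all 9 groups with the line as a block (9), without the 3 lines of shared origin (16), with only lines that have all 9 arrays (14) and without the 2 prostate lines (1). Signal over background was not part of the files used here, so the limit for dim genes rests on the lowest 40% left out. Of 370 values of named genes, 22 lost their call over the mean of probe sets, 6 with quantile normalization and 16 without the 12 line names, and 0 reversed.

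Where counts moved, the cause follows from the alternative's construction only for the thresholds, and otherwise the cause was not tested. With no minimum size 3439, 6765 and 6661 genes passed at 1000 nM (2, 6 and 24 h), 3202, 7002 and 7621 at 5000 nM, 299, 4572 and 6950 between doses, 5234 and 4396 between times at 1000 nM (6 against 2 h, 24 against 6 h), 5512 and 4839 at 5000 nM, and 1778 in untreated cells. With a 2-fold minimum these were 1, 99 and 40, then 7, 378 and 843, then 0, 4 and 197, then 20 and 5, then 124 and 123, and 1. The 0 between doses at 2 h stands beside 1482 genes at an unadjusted p under 0.05 from limma.

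The line is the block of every paired test. Fitted with no replicate block, 0 genes passed between doses at 2 h and 47 at 6 h, 113 and 65 between times at 1000 nM, 553 and 466 at 5000 nM, and 6 in untreated cells, and the fit without the pairing moved no other count by over 1.5 times.

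Without the 12 line names 390 and 281 genes passed between times at 1000 nM, 1320 between 24 and 6 h at 5000 nM, 45 in untreated cells and 1393 in the tissue test, and 6 lists were called at 1000 nM and 2 h. At 1000 nM and 24 h the tissue test called 219 genes and the leukemia test 165. Without the leukemia lines the tissue test called 162, and without these and the 12 names 868. With an estimated correlation camera called 0 lists at 1000 nM at 2, 6 and 24 h and 1, 1 and 0 at 5000 nM, and the lineage markers lost their call, with adjusted p = 0.55 for melanocyte markers in melanoma and 0.55 for haematopoietic markers in leukemia.

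Leaving out each line in turn gave 42 to 47, 653 to 699 and 402 to 452 genes at 1000 nM (2, 6 and 24 h), 92 to 104, 1470 to 1513 and 2481 to 2575 at 5000 nM, 1 to 1, 70 to 80 and 1017 to 1137 between doses, 228 to 264 and 124 to 152 between times at 1000 nM, 806 to 869 and 724 to 851 at 5000 nM, and 13 to 27 in untreated cells, where M14 (26), SK-MEL-5 (26) and T-47D (27) moved it by over 1.5 times. The leukemia count ran from 376 without CCRF-CEM to 756 without SR. The adjusted p of melanocyte markers ran from 0.0014 to 0.0077 and that of haematopoietic markers from 0.00041 to 0.015.

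The balance of higher and lower calls changed sides under several alternatives. Median centring moved the share of higher calls from 54.0% to 45.8% and from 57.7% to 49.4% (1000 nM, 6 and 24 h), from 55.1% to 49.4% (5000 nM, 6 h), from 48.6% to 54.7% (between doses, 24 h), from 41.6% to 51.7% (24 against 6 h, 5000 nM), from 41.2% to 23.8% (untreated) and from 44.9% to 26.5% (leukemia), and quantile normalization moved the share between doses at 24 h to 51.0%. Without the block the majority turned at 1000 nM and 24 h (147 higher, 168 lower), between 6 and 2 h at both doses (32 and 81, 244 and 309) and in untreated cells (5 and 1). At 5000 nM and 24 h, 1265 higher and 1255 lower, it turned without the block (1190 and 1208), over the mean of probe sets (1133 and 1137), with the lowest 40% left out (1068 and 1213) and without the 12 names (1408 and 1418). With no minimum size it turned at 1000 nM and 24 h (3154 and 3507), between doses at 6 h (2282 and 2290) and 24 h (3640 and 3310), between 24 and 6 h at 1000 nM (1939 and 2457) and in untreated cells (1143 and 635, and 1 and 0 with a 2-fold minimum). In the leukemia test it turned with the lowest 40% left out (230 and 158) and at 1000 nM (149 and 16).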

Other observations

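The 3 relations across lines and the test of the level before treatment were chosen after the data were seen, while the tests of a compressed scale and of drift in untreated cells were written before their results.

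Some genes varied far more between lines than the panel means show, here at 5000 nM and 24 h in the 47 lines outside the 12 names, picked by their SD over lines. CGA, the alpha chain of the glycoprotein hormones, changed by 1.32 ± 2.09 (SD, n = 47), with 8.36 in the melanoma line UACC-257 and a rise of 1 log2 unit or more in 14 lines, from an untreated mean of 4.61. FABP4, a fatty acid carrier of fat cells, changed by 2.19 ± 2.35, with such a rise in 24 lines and 8.25 in UACC-257, and the hormone gene CCK by 1.79 ± 2.07, with such a rise in 22 and 6.25 in the lung line NCI-H23, from untreated means of 3.96 and 4.30. STC1 changed by 2.77 ± 2.36, by 1 or more in 33 lines and by 8.34 in the melanoma line MALME-3M, and TUBB2B, a tubulin of neurons, by 2.71 ± 2.05, by 1 or more in 35 lines and by 7.21 in the leukemia line K-562, from 6.14 and 6.18. CD24 (1.16 ± 2.00), with an untreated mean of 9.58, rose by 1 or more in 18 lines and by 6.93 in SK-MEL-28, and the collagenase MMP1 (1.10 ± 1.93) in 14 lines and by 6.34 in the same line.

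Others fell, or went both ways. ERBB3, a receptor of the EGFR family, had a mean of 0.12 ± 1.95, was higher by 1 log2 unit or more in 17 lines and lower in 10, and ran from 3.11 in the renal line UO-31 to -4.80 in the colon line COLO-205. NNMT, which methylates nicotinamide, had -1.09 ± 2.07, was lower by 1 or more in 24 lines and higher in 3, with 4.90 in HCC-2998 and -4.73 in HT29, both colon lines. LPXN, an adaptor of focal adhesions, had -1.52 ± 1.93, was lower by 1 or more in 24 lines and higher in 3, with -6.15 in COLO-205. The COLO-205 array at 5000 nM and 24 h, behind both of these lowest values, stood apart: it had the lowest interquartile range of all arrays, 3.37 log2 units against a median of 4.27, and correlated at no more than 0.592 with any other array of its line.

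A hypothesis is that vorinostat may bring genes that set a line apart nearer to their level in the other lines. In each of the 47 lines the change at 5000 nM and 24 h was correlated over 7178 genes with the line's untreated level at 2 h, both relative to the other lines, so the level came from other arrays than the change. The mean correlation was -0.35, negative in 47 of 47 lines (-0.58 to -0.01), while 1000 shuffles of the lines gave -0.06 to 0.05. Falls of genes high in a line and rises of genes low in it both make it negative, and they were not told apart. These correlations are over genes, which are not independent replicates. A compressed scale of whole treated arrays was argued against, since quantile normalization left -0.33. That step cannot undo a compression of single genes near the ends of the scale, so it does not decide about these. Drift of the untreated cells was argued against as well, since their change from 6 to 24 h gave -0.05. The value was -0.14 at 1000 nM and 24 h, -0.23 at 5000 nM and 6 h, and -0.18 over the 3263 genes that stayed between 6 and 12 on the log2 scale in all 47 untreated lines, so the ends of the array scale may add to it.

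Of 3 relations tested across these lines 1 passed. Response size at 6 h went with that at 24 h at 5000 nM (r = 0.41, permutation p = 0.005, rho = 0.41, permutation p = 0.006, 45 lines, adjusted p = 0.015, r = 0.50 without the 2 farthest lines). The relation of the CDKN1A change to the mean of the DNA replication list did not pass and stays undecided (r = 0.14, permutation p = 0.35, rho = 0.19, permutation p = 0.19, adjusted p = 0.35, r = 0.17 without the 2 farthest). The relation of the FOS change at 2 h to the response size at 24 h did not pass either and is undecided too (r = 0.16, permutation p = 0.28, rho = 0.01, permutation p = 0.96, adjusted p = 0.35, r = -0.06 without the 2 farthest).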
